A study of Daphnia pulex with 8 samples.

How the data were processed

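CAGE (cap analysis of gene expression) reads the first bases of capped transcripts, so that each tag marks the position at which transcription of an RNA started. The series held 8 libraries from whole animals of the Daphnia pulex clone PA42, aged 8 ± 1 days: 3 libraries of asexual (parthenogenetic) females, 3 of sexual (pre-ephippial) females and 2 of males. Per the labels' protocols, each library came from a separate collection of pooled animals, and total RNA was reverse transcribed from random primers, captured by its biotinylated cap and ligated to barcoded linkers, without an amplification step being described. Per the submitters' processing notes, BWA 0.6.2-r126 was among the tools used; the genome build and the other mapping settings are not given in the sources used here.

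The series gave 2 kinds of value. Per the file headers, the authors deposited a table of tag counts at single positions for each library, with scaffold, position and strand. A second deposited table gave the same positions scaled to library size (TPM by its header, which for tags is the same as CPM), and its values equal the counts divided by the library total. All values of that table (100.0%) came out as whole tags within a tolerance of 0.001 tags when multiplied back, and 100.0% equalled the count table. The count test on the recovered tags called 8728, 6219, 5195 and 8133 clusters in the contrasts below, the numbers that the count table gave.

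Positions were grouped into tag clusters once, from all 8 libraries. A position was kept at 1 TPM or more in at least 2 libraries, kept positions on 1 strand up to 20 bp apart were joined, and all tags between a cluster's ends were summed per library. Coordinates are 1-based as in the deposited tables. The width of a cluster is the distance between the 0.1 and 0.9 quantiles of its tags, and clusters up to 10 bp wide are called narrow here. A cluster was called downstream of a stronger one where a cluster with at least 10 times its tags began up to 5 kb upstream on the same strand, since such tags can come from within a transcript.

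Levels were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05), with all 8 libraries in 1 fit and state as the only factor, for 4 contrasts. Level changes are given as TPM means with their SD. Fold changes against a state with 0 tags are lower bounds computed with 3 tags over that state's libraries, and ratios against 1 to 3 tags are given for the pooled tags with their exact 95% counting interval; both cover counting error only, while p-values measure the spread between these libraries. Start site use within clusters was tested with edgeR's diffSpliceDGE on positions with at least 10 tags (Simes p per cluster, Benjamini-Hochberg over clusters). Widths were compared with exact permutation tests of per-library values after thinning each library to the smallest library's total, over clusters with at least 20 tags in every library. Shares of narrow clusters were compared with Fisher's exact test and with 10000 draws of clusters that were not called, matched on 10 classes of tag number. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, DESeq2 1.42.0 and limma 3.58.1 were also used.

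The clusters named by position are, for each contrast, the 2 with the largest rise and the 2 with the largest fall among clusters that passed the test, had at least 5 TPM in the higher state and showed no overlap between the libraries of both states. That rule was fixed before the data were examined; any other cluster named was chosen after its values were seen. The rule was meant for named genes. The gene table used here belongs to another assembly (its header says ASM2113471v1), and no genome or annotation of the build was used, so clusters carry no gene names, and comparisons of gene lists, sums per gene and the test for TATA boxes and other core promoter motifs were not analysed here.

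The tests were tested on simulated data with known changes. With 100 clusters changed 4-fold, edgeR recovered 67% in males against asexual females, 55% in males against sexual females, 69% in males against the mean of both female states and 72% in sexual against asexual females, with 22454, 22454, 22454 and 22522 clusters tested; at 2-fold it recovered 15%, 11%, 18% and 14%. False calls made up 10.9%, 5.71%, 6.45% and 6.52% of calls. For start site use, exchanging the 2 strongest positions of 200 clusters among 14015 was recovered in 60.5%, 55% and 67% of cases for males against asexual females, males against sexual females and sexual against asexual females, and 20.9%, 11.3% and 19.3% of calls were false, above the nominal share.

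Replicates of a state were compared by chi-square over clusters: the statistic per degree of freedom was 7.17 to 30.1 within states and 82.3 to 157 between states, so no 2 libraries agreed within sampling noise. Nothing in the labels pairs equal replicate numbers of different states. Alternatives to these choices are given in the closing section.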

Results

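Transcription start sites were mapped by CAGE in whole Daphnia pulex of 1 clone in 3 reproductive states: females that reproduce asexually, females about to produce sexual resting eggs, and males. Asexual female replicates 1, 2 and 3 had 13064971, 7427970 and 10856579 tags. Sexual female replicates 1, 2 and 3 had 9332995, 10672145 and 5757705, and male replicates 1 and 2 had 7830664 and 9077385. A count of 3 tags, the limit that a count of 0 allows, corresponded to 0.230 to 0.521 TPM in single libraries. The series set out to describe the landscape of start sites and active promoters in these states.

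Start sites lay mostly in clusters, and clusters with few tags were the narrowest. The 74020414 tags fell on 2332582 positions, of which 53.0% carried 1 tag, and 90.7% of the tags lay in 26182 tag clusters on 453 scaffolds, 13141 on the plus and 13041 on the minus strand. The median cluster was 2 bp wide, 75.6% of the clusters were up to 10 bp wide, and 46.5% held a single position. Of all clusters, 9521 (36.4%) lay downstream of a cluster with at least 10 times their tags. They held 4.36% of all tags, and without them the median width was 4 bp and 69.4% were narrow. Among the latter clusters with at least 100 tags, the narrow share fell from 97.7% (median 1 bp) at 100 to 155 tags to 41.6% (median 19 bp) at 3636 to 7881 tags, and was 53.2% (median 8 bp) above that. The rule for clusters itself favours this trend. With few tags, few positions can reach 1 TPM in 2 libraries, so such a cluster can hardly be wide.

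The 3 states formed 3 separate groups of libraries. Log2 cluster levels correlated across clusters with r of 0.964 to 0.985 between libraries of a state, 0.918 to 0.933 between asexual and sexual females, 0.892 to 0.903 between males and sexual females, and 0.863 to 0.893 between males and asexual females. Clusters are not independent replicates, so these values describe the libraries.

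**Figure D1:**
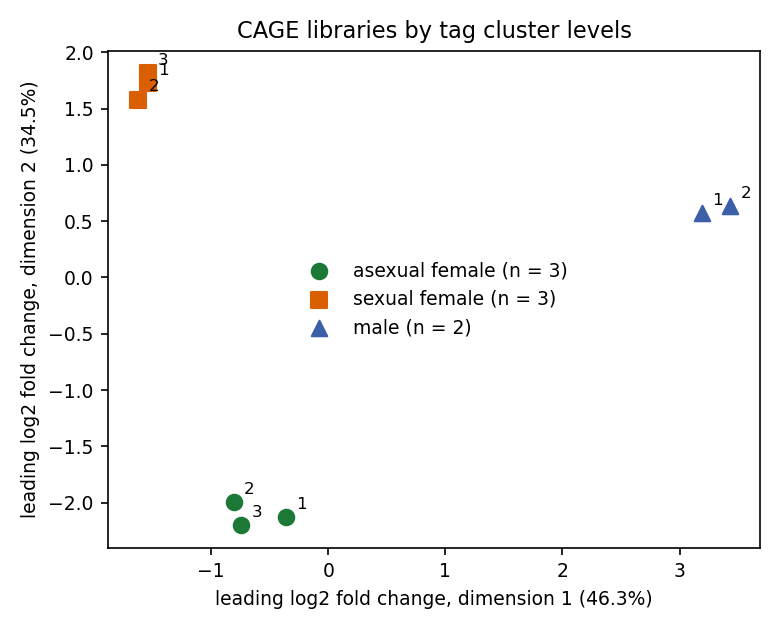
Multidimensional scaling of the 8 libraries by leading log2 fold change of tag cluster levels (log2 units on both axes; the share of variance is given for each axis, 46.3% and 34.5%). Each point is a library, numbered by replicate; males lie at 3.19 and 3.43 on dimension 1 and all female libraries below 0.

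Males against asexual females gave the largest set of differences. The 4 most abundant start regions of asexual females were lower in males, although they were chosen after their values were seen. The next, on scaffold 24 (1295875 to 1295889, plus), did not pass (log2 fold change −0.52, adjusted p 0.0979, edgeR). The most abundant, on scaffold 958 (4255 to 4278, plus), had a log2 fold change of −2.49 ± 0.27 (SE). Those with the largest falls among them are given next. A cluster on scaffold 958 (1393 to 1437, minus strand) held 28836 ± 3984 TPM (SD, n = 3) in asexual females and 414 ± 118 (n = 2) in males, log2 fold change −6.07 ± 0.35 (SE). A cluster on scaffold 47 (127024 to 127078, minus) held 18248 ± 2181 TPM and 92.8 ± 23.1 TPM, log2 fold change −7.57 ± 0.32 (SE). The strongest start region of males, on scaffold 10571 (353 to 375, minus), held 37938 ± 4160 TPM in males and 44.4 ± 59.1 TPM in asexual females, of which replicate 1 alone had 112.6.

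By the rule for named clusters, the largest rises were on scaffold 10 (678600 to 678611, minus) and scaffold 3 (199612 to 199615, minus). The first had 24.8 ± 1.41 TPM in males and 0 tags in asexual females, at least 259-fold higher in males. The second had 137 TPM in male replicate 1 and 25.4 in male replicate 2, against 1 tag in asexual females (ratio 2412, counting interval 432 to 95349), and its log2 fold change of 10.86 became 9.18 without male replicate 1 and 12.47 without asexual female replicate 1. The largest falls were 2 clusters on scaffold 47, at 125359 to 125377 and 122701 to 122733 on the minus strand. They had 20.4 ± 3.92 and 15.5 ± 5.98 TPM in asexual females and 0 tags in males, at least 115-fold and at least 87.5-fold lower. Both lay downstream of the abundant scaffold 47 cluster named above. The adjusted p-values of the 4 clusters in edgeR's quasi-likelihood test were 1.42e-05, 6.89e-05, 1.89e-05 and 3.47e-05.

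Of 24572 clusters tested, 8728 differed between males and asexual females (adjusted p under 0.05, edgeR), 3847 higher and 4881 lower in males. Counting only clusters more than 8-fold apart in mean TPM, with the lower state set to no less than 3 tags, 381 were higher and 1228 lower in males. Without clusters downstream of a stronger one, these numbers were 236 and 814. The balance over all sizes of change depended on the scaling: 44.1% of the called clusters were higher in males in the full fit, 54.3% when the data were scaled and fitted anew without clusters downstream of a stronger one, and 54.4% when this was done without single-position clusters. Leaving the downstream clusters out of the calls of the full fit gave 2721 higher and 3634 lower.

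**Figure D2:**
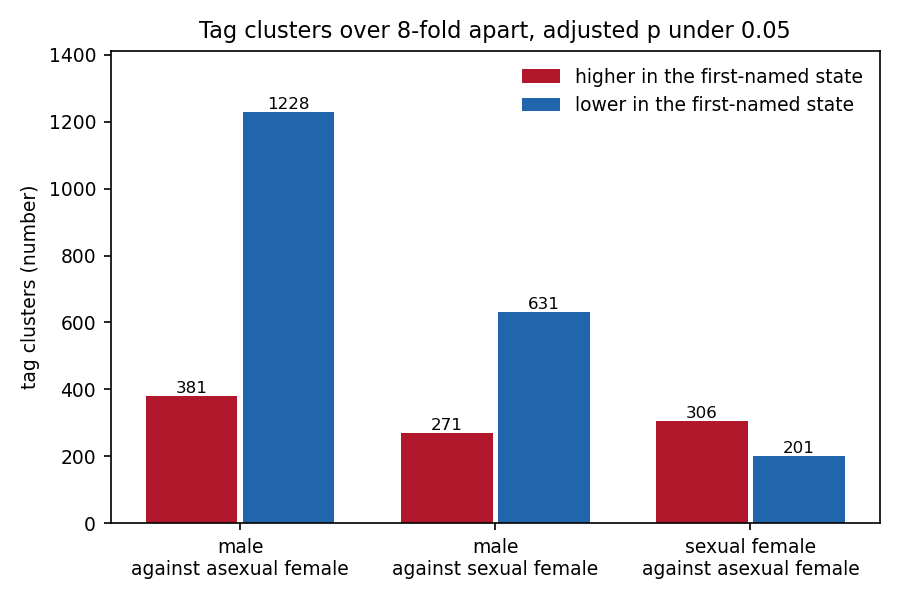
Number of tag clusters with an adjusted p under 0.05 and more than 8-fold apart in mean TPM (lower state at no less than 3 tags) for each pair of states; bars give clusters higher and lower in the first-named state. Males had 1228 lower and 381 higher clusters against asexual females. Clusters were formed from positions at 1 TPM or more in at least 2 libraries, and males had only 2 libraries.

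Males against sexual females differed by strong start regions on both sides. A cluster on scaffold 67 (52757 to 52789, minus) held 8329 ± 1266 TPM in males (n = 2) and 2.08 ± 2.12 TPM in sexual females (n = 3), a 4005-fold difference in mean TPM. Sexual female replicates 1, 2 and 3 had 4.50, 1.22 and 0.521 TPM there, and the log2 fold change of 11.86 became 13.06 without replicate 1. The scaffold 3 cluster at 199612 had 0 tags in sexual females, at least 696-fold below the male mean, to which male replicates 1 and 2 gave 137 and 25.4 TPM. Its log2 fold change of 12.57 became 10.92 without male replicate 1. On the other side, a cluster on scaffold 25 (949274 to 949300, plus) held 2961 ± 159 TPM in sexual females and 1 tag in males (ratio 49559, counting interval 8895 to 1957496), and its log2 fold change of −15.35 became −17.83 without male replicate 1 and −14.35 without male replicate 2. A cluster on scaffold 13 (738314 to 738319, plus) held 531 ± 32.8 TPM in sexual females and 0 tags in males, at least 2990-fold lower in males. The adjusted p-values of these 4 clusters in edgeR's quasi-likelihood test were 0.00018, 0.000137, 1.02e-05 and 9.37e-06.

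In this contrast 6219 clusters passed the test, 3066 higher and 3153 lower in males. With the lower state at no less than 3 tags, 271 were more than 8-fold higher and 631 more than 8-fold lower in males, or 196 and 442 without clusters downstream of a stronger one. The limit given above for starts used only in males holds for these numbers too.

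Among the many start regions that differed between sexual and asexual females was a small set of very strong ones nearly unused in asexual females. The strongest, chosen after its values were seen, lay on scaffold 13 (635411 to 635499, minus) and held 19710 ± 3034 TPM in sexual females and 57.9 ± 44.5 TPM in asexual females (n = 3 each), log2 fold change 8.49 ± 0.68 (SE), adjusted p 1.7e-05 in edgeR's quasi-likelihood test. The 3 most abundant start regions of asexual females were all lower in sexual females. The scaffold 958 clusters at 4255 to 4278 (plus) and 1393 to 1437 (minus) fell from 42585 ± 1140 to 15247 ± 2547 TPM and from 28836 ± 3984 to 9779 ± 2073 TPM, and the scaffold 47 cluster at 127024 to 127078 fell from 18248 ± 2181 to 5599 ± 558 TPM. Their log2 fold changes were −1.40 ± 0.22, −1.48 ± 0.24 and −1.63 ± 0.20 (SE), with adjusted p-values of 0.00149, 0.00159 and 0.000378 (edgeR).

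By the rule for named clusters, the largest rises were on scaffold 13 (634818 to 634830, minus), with 15.9 ± 11.4 TPM against 0 tags and at least 167-fold higher in sexual females, and on scaffold 25 (993509 to 993514, plus), with 87.8 ± 67.2 TPM against 2 tags (ratio 1171, counting interval 324 to 9678). The scaffold 13 cluster lay downstream of the strong one at 635411. Its log2 fold change of 10.26 became 9.52 without sexual female replicate 1, and that of the scaffold 25 cluster, 10.23, ranged from 9.37 without sexual female replicate 3 to 12.76 without asexual female replicate 2. The largest falls were a single position on scaffold 91 (310755, minus), with 5.33 ± 0.972 TPM in asexual females and 0 tags in sexual females (at least 45.7-fold lower), and a cluster on scaffold 12 (1267644 to 1267647, minus), with 8.77 ± 1.29 TPM against 1 tag (ratio 232, counting interval 41.3 to 9186), whose log2 fold change of −7.34 became −9.28 without sexual female replicate 2. Adjusted p-values were 0.000289, 3.78e-05, 0.000228 and 1.48e-05 in edgeR's quasi-likelihood test.

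Among 24572 clusters, 5195 differed between sexual and asexual females, 2163 higher and 3032 lower in sexual females. More than 8-fold apart were 306 higher and 201 lower, or 173 and 136 without clusters downstream of a stronger one. The number fell to 3164 without asexual female replicate 1 and to 3317 without asexual female replicate 2. The median log2 fold change of all clusters was −0.10, and the balance of directions changed with the libraries and clusters used to scale the data. In the full fit 41.6% of calls were higher in sexual females. The share was 54.8% with only the 6 female libraries, 53.9% without clusters downstream of a stronger one and 54.2% without single-position clusters. It was 31.7% with limma on the deposited TPM, which changed the scaling, the log scale and the test together.

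Males were also set against the mean of both female states, a contrast that can call clusters differing from 1 female state alone. The scaffold 13 cluster at 635411 passed it (log2 fold change −4.76, adjusted p 0.000354, edgeR). It did not pass for males against asexual females (log2 fold change −0.51, adjusted p 0.517, edgeR). The 4 clusters named by the rule were the scaffold 3 and scaffold 67 clusters above, higher in males, and the scaffold 25 and scaffold 13 (738314) clusters, lower in males. The latter were nearly specific to sexual females, with 8.01 ± 6.23 and 1.55 ± 1.34 TPM in asexual females against 2961 ± 159 and 531 ± 32.8 TPM in sexual females. In all, 8133 clusters passed the test, 3914 higher and 4219 lower in males. Without male replicate 2 the number was 5388. Log2 fold changes were 11.72 for scaffold 3 (10.05 without male replicate 1), 10.90 for scaffold 67 (12.61 without asexual female replicate 1) and −11.02 for scaffold 25 (−13.50 without male replicate 1).

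Start regions used almost exclusively in 1 state carried a visible share of its transcripts. With a mean of at least 1000 TPM in 1 state and more than 20 times the mean of each other state, thresholds set after the data were seen, 7 clusters were restricted to sexual females and held 4.04% of their tags. A further 5 were restricted to males and held 5.25%, and 0 were restricted to asexual females. At a minimum of 10 TPM the numbers were 74, 60 and 20. Of the sexual female clusters, 4 lay together on scaffold 10 between 520876 and 524734. These were 522697 to 522713 (plus), 524723 to 524734 (minus), 520876 to 520898 (minus) and 522903 to 523030 (plus), with 7833 ± 1240, 4661 ± 1120, 2508 ± 661 and 1428 ± 446 TPM in sexual females. In males the same clusters held 2.39 ± 0.416, 96.6 ± 37.0, 1.33 ± 0.641 and 0.421 ± 0.128 TPM. The other male clusters lay on scaffold 36 (524767 to 524772, plus), scaffold 67 (462374 to 462418, plus) and scaffold 18 (728348 to 728370, minus), with 3221 ± 754, 1737 ± 662 and 1261 ± 9.80 TPM in males and 3.18 ± 1.41, 0.642 ± 0.115 and 1.46 ± 0.653 TPM in sexual females.

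**Figure D3:**
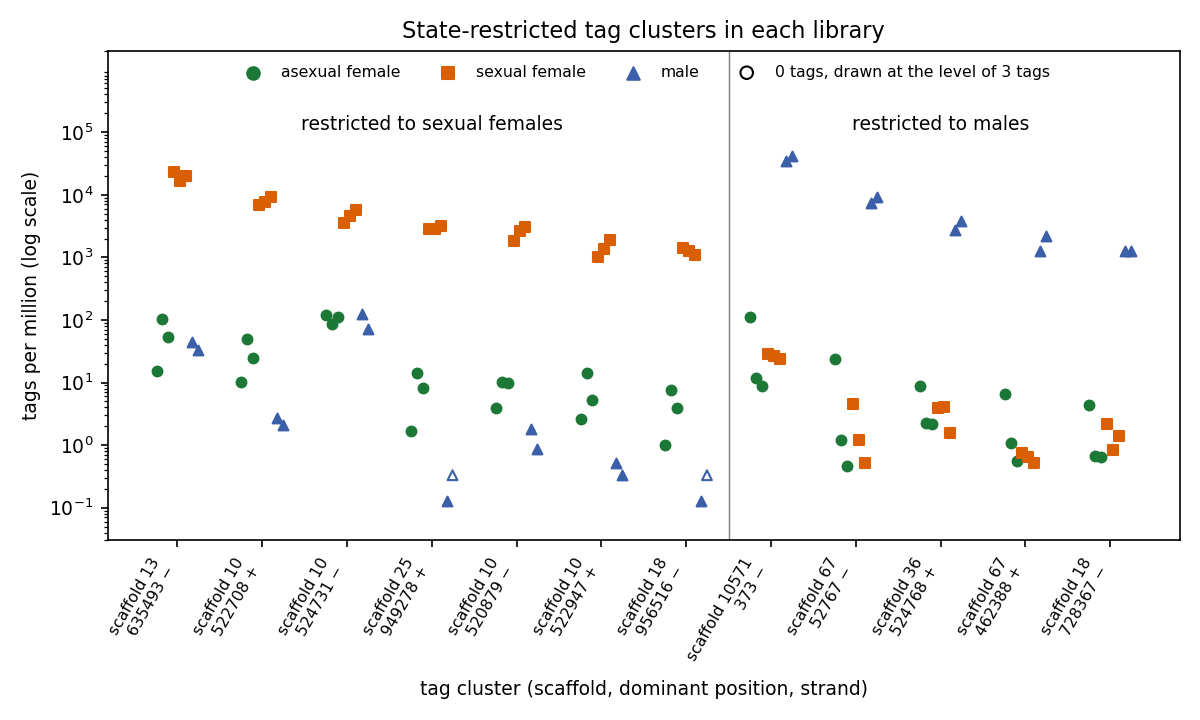
Level of each of the 7 clusters restricted to sexual females and the 5 restricted to males in every library, in TPM on a log axis; each symbol is a library and open symbols mark 0 tags, drawn at the level of 3 tags. Among the male clusters, asexual female replicate 1 lies above both other asexual female libraries in each case.

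Close divergent start regions that both differed between states mostly moved in 1 direction, and close same-strand ones did so more often. Among clusters not downstream of a stronger one, 527 divergent neighbours lay up to 300 bp apart (median 204 bp). Where both partners differed between males and asexual females, 77 of 89 pairs (86.5%) moved in 1 direction, against 47 of 90 (52.2%) of divergent neighbours 3000 to 10000 bp apart (Fisher's exact test, two-sided, p = 7.36e-07, adjusted over 4 contrasts 2.95e-06). For males against sexual females, the numbers were 19 of 21 and 33 of 65 (adjusted p = 0.00212). For sexual against asexual females, they were 19 of 21 and 22 of 36 (adjusted p = 0.0304). Over all pairs, called or not, the log2 fold changes of partners up to 300 bp apart correlated only weakly, with r of 0.248, 0.188 and 0.213 in these 3 contrasts, against 0.266, 0.307 and 0.251 at 300 to 1000 bp and 0.0317, −0.0392 and 0.149 at 3000 to 10000 bp. Same-strand neighbours up to 300 bp apart that both differed moved in 1 direction in 97.3%, 98.9% and 96.9% of cases in these 3 contrasts. The agreement was therefore not particular to divergent pairs. Convergent neighbours that close were too few to compare, with 1 such pair between males and asexual females. Pairs are not independent replicates, so these p-values describe the pairs in these libraries.

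Start regions shared by all libraries were slightly narrower in males. At 9044 clusters with at least 20 tags in every library after thinning, the mean width was 17.8 ± 0.0280 bp in asexual females, 17.5 ± 0.0841 bp in sexual females and 16.9 ± 0.162 bp in males. The median width, the planned measure, was 12 bp in each female library and 11.25 ± 0.354 bp in males (exact permutation test over all 3 states, 560 arrangements, p = 0.0357). The same exact test on the mean width, chosen after seeing the data, gave p = 0.00357. No pair of states could go below the smallest exact p of 0.1 that these sample sizes allow. The difference in the median rested on whole base pairs and did not pass the test in most other settings, as with no thinning (exact p = 1.00), and it did not pass with any 1 library left out, while the mean width passed in all of these settings. Tags within the shared clusters were not matched between libraries. Cluster ends were set by positions at 1 TPM or more in at least 2 libraries. Outer starts used only in males had to reach this in both male libraries, which can lower male widths. The size of this effect was not tested.

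**Figure D4:**
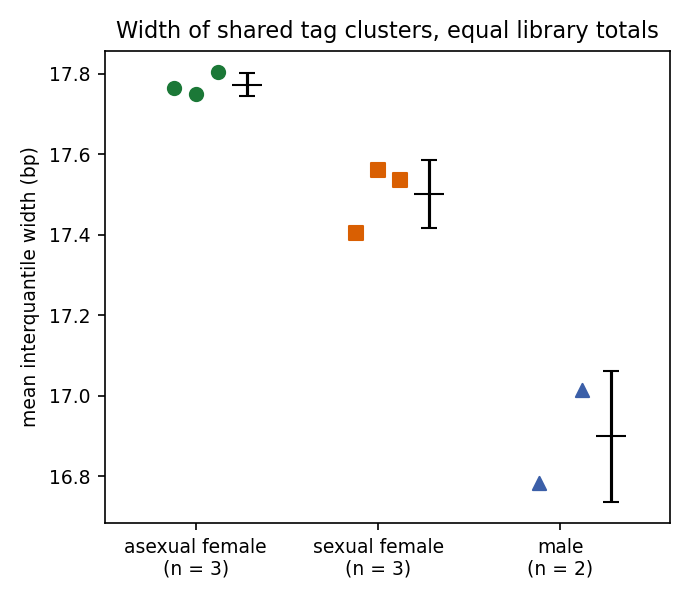
Mean interquantile width in bp of 9044 shared tag clusters in each library after thinning to equal library totals (the axis does not start at 0); points are libraries and the black bars give the mean and SD of each state. Both male libraries lie below all 6 female libraries.

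Start regions higher in males, and those that differed between the female states, were more often narrow than others with as many tags. Of clusters with at least 100 tags that were not downstream of a stronger one, 1416 of 1701 (83.2%) of those more than 2-fold higher in males than in asexual females were up to 10 bp wide, against 62.3% of 7828 clusters not called and 63.3% after matching on tag number (permutation p = 0.0002, the smallest that the 10000 draws can give). Clusters more than 2-fold lower in males than in asexual females were narrow in 58.9% of cases, against 63.8% after matching (permutation p = 0.0002). Those more than 8-fold lower were instead narrow in 76.6% of cases, against 68.7% after matching (permutation p = 0.0002). Against sexual females, clusters higher in males were narrow in 86.6% and matched ones in 61.5% of cases. Those lower were narrow in 67.9% and matched ones in 60.7% of cases. Clusters lower in males than in the mean of both female states were narrow in 62.6% and matched ones in 62.9% of cases (permutation p = 0.775). Clusters higher in sexual than in asexual females were narrow in 79.7% of cases and those lower in 78.0%, against 57.0% and 63.7% after matching. Widths from male tags alone cover another set, the clusters with at least 50 male tags, a limit that a fall in males itself affects. They were taken at positions with at least 10 tags over all libraries, a number that female tags help to reach. There, 39.4% of 1031 clusters lower than in asexual females were narrow and 59.2% of matched ones (permutation p = 0.0002), and 56.0% of 620 lower than in sexual females and 55.5% of matched ones (permutation p = 0.835). Clusters are not replicates, so the permutation p-values describe the clusters of these libraries.

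**Figure D5:**
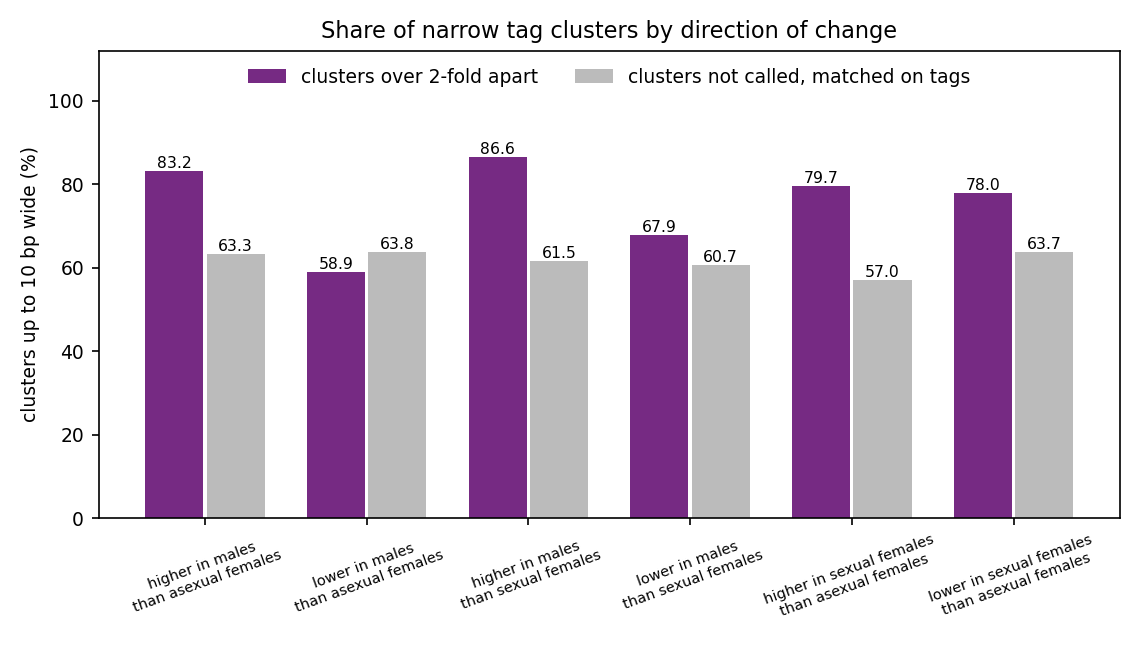
Percent of clusters up to 10 bp wide among those more than 2-fold apart (adjusted p under 0.05) in each direction and contrast, and among clusters not called, matched on tag number. The share was 83.2% for clusters higher in males than in asexual females and 63.3% for the matched clusters.

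A small part of the start regions shifted the positions they used. Of 14015 clusters with at least 2 tested positions, 751 (5.36%) differed in start site use between males and asexual females (adjusted p under 0.05, edgeR). Males and sexual females differed at 322 (2.30%), and sexual and asexual females at 308 (2.20%). Most shifts were short, with a median change of the mean position of 1.74, 0.749 and 0.878 bp. Of the 751, 51 moved by at least 10 bp with at least 5 TPM in both states, and 44 of these moved upstream in males. Only 325 of the 751 did not also pass the test for a difference in level. The following clusters were chosen after their values were seen. On scaffold 15 (361174 to 361277, minus), the strongest position was 361177 in both female states and 361251 in males. The mean position lay at 361215 ± 0.224 in asexual females and 361245 ± 2.24 in males, −29.9 bp in the direction of transcription (adjusted p = 2.34e-06, edgeR). Its level was also lower, with 153.8 TPM in asexual females and 42.7 TPM in males (log2 fold change −1.79). Fewer starts at the downstream end cannot be told apart from a move upstream. On scaffold 11 (1963849 to 1963922, minus), the strongest position was 1963905 in asexual females and 1963869 in sexual females and males (adjusted p = 0.00409 for sexual against asexual females, edgeR). Leaving out 1 male library cut the 751 to 256 (replicate 1) or 423 (replicate 2). The 322 became 158 without male replicate 1, 187 without sexual female replicate 1 and 191 without sexual female replicate 2. The 308 became 185, 196 and 184 without asexual female replicate 1, sexual female replicate 1 and sexual female replicate 2.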

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

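Tags outside every tag cluster took no part in the comparisons and were looked at for that reason. They amounted to 9.34% of all tags, 6914398 of 74020414. All of them lay at positions that did not reach 1 TPM in 2 libraries, so the rule for clusters itself leaves them out. Their share was 10.2 ± 0.627% (SD, n = 3) in asexual females, 8.33 ± 0.269% (n = 3) in sexual females and 8.99 ± 1.26% (n = 2) in males.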

How the results depend on the processing

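The alternatives with recovered counts, without clusters downstream of a stronger one, without single-position clusters, with the mean width and with the cluster-level F test were chosen after seeing the data, as was the test of splits for cluster levels. The counts of clusters that differ in level stayed within 1.5 times their value under every alternative run, with these exceptions. At an adjusted p under 0.01 they were 5388, 3322, 2340 and 4782 for males against asexual females, against sexual females, sexual against asexual females and males against both female states. With 1 library left out, sexual against asexual females ranged from 3164 to 5649 and males against both female states from 5388 to 8197. The other 2 ranged from 6355 to 9130 and from 4170 to 5784. Where a state kept 1 male library, it was assumed to vary like the other states. Of 387 values of named clusters and pairwise width differences under alternatives, 375 counted as unchanged and 12, all width differences, moved; 0 reversed. For named clusters this covers direction and call only. On the log2(TPM + 1) scale of limma most sizes shrank, as from 10.86 to 4.69 for scaffold 10 (678600), while scaffold 67 against both female states went from 10.90 to 11.26. With a joining distance of 40 bp scaffold 13 (634818) went from 10.26 to 7.95 and scaffold 47 (122701) from −10.14 to −8.22. Whether replicate numbers shared between states pair the libraries is not settled. Deviations of equal-numbered asexual and sexual female libraries correlated with r of 0.152, 0.0139 and 0.182, and those of unequal-numbered ones with r from −0.209 to 0.0875. Equal-numbered male libraries gave 0.0530 and −0.172 with asexual females and 0.118 and 0.0868 with sexual females. With the number as a replicate block the counts were 8427, 5875, 5226 and 7665, and for start site use 545, 226 and 267.

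The difference in median width (exact p = 0.0357) was lost with 0.05 to 0.95 quantiles, no thinning or a joining distance of 10 bp (exact p = 1.00 each), at 10 or 50 tags per cluster (exact p = 0.486 each) and with 40 bp (exact p = 0.25), and ranged from exact p = 0.0952 to 1.00 with 1 library left out. Males minus asexual females was −0.75 bp in the median, 0 bp with 0.05 to 0.95 quantiles or 10 bp, −0.333 bp with no thinning, −0.5 bp with 40 bp, −0.667 bp at 10 or 50 tags and −0.333 to −1 bp with 1 library left out. The mean width gave exact p = 0.00357 in each setting with all libraries and 0.00952 to 0.0143 with 1 left out. Clusters with shifted start site use in males against asexual females numbered 1390 with the cluster-level F test. With positions joined to 5 bp, males against sexual females gave 147 and sexual against asexual females 119. With 1 library left out the 3 contrasts ranged from 256 to 797, 158 to 322 and 184 to 349. The cause of these changes was not tested. The scaling that moved the directions of change also moved the median log2 fold change, from −0.10 to 0.03 for sexual against asexual females with only the female libraries and from 0.00 to 0.14 for males against asexual females without clusters downstream of a stronger one. Sums per gene, the motif tests and the gene lists were not run.

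The 6 female libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split (1 of 10) gave 5195 clusters that differ in level and the highest other split 0; for start site use it (1 of 10) gave 308 and the highest other split 95. Depth set the level of 3 tags at 0.230 to 0.521 TPM; its effect on detection was not separated from replicate number and spread.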

Other observations

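Except for the widths from male tags alone, the tests below were chosen only after the results were seen.

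Clusters more than 8-fold apart by the fitted change, and not downstream of a stronger one, lay together on the genome in each pair of states and both directions (permutation p = 0.001, the smallest of 1000 permutations). For clusters higher in sexual than in asexual females, 19 windows of 50 kb held at least 3, 86 of 182 clusters, against a mean of 0.351 and a highest value of 4 over the permutations, and a window on scaffold 8 held 12 of 24 tested, between 15889 and 39347, 6 on each strand. Several clusters of 1 transcription unit could give such runs. With 1 cluster kept per chain of same-strand clusters up to 3 kb apart, 7 windows still held at least 3 of 110 such chains, against at most 3 in the permutations. Same-strand runs with gaps up to 3 kb thus do not alone account for the grouping. Clusters of 1 unit farther apart or on the other strand still counted separately, so transcription units stay open without an annotation. Of the other 5 sets, 4 also passed with chains (permutation test, adjusted p = 0.0045 to 0.0218), and clusters lower in males than in asexual females did not (7 windows, permutation p = 0.196). Reads shared between near-identical copies stay open, since no genome was used, and so does regulation shared by neighbouring genes.

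At 17 clusters with at least 50 TPM in males and less than 1 part in 100 of that in sexual females, asexual female replicate 1 held a median 0.371% of the male level (quartiles 0.297% and 0.415%). Expression shared by all asexual females is argued against for the set by replicates 2 and 3, with medians of 0.0309% and 0.0318%, although scaffold 32 (184315 to 184320, minus) had 42, 23 and 45 tags in replicates 1, 2 and 3. Tags or RNA of male replicate 2 were tested at single positions with at least 10 TPM, chosen without the asexual female libraries. Asexual female replicate 1 held a median 1.19% of the level at 20 positions restricted to male replicate 2. It held a median of 0% at 12 restricted to male replicate 1 (permutation p = 0.0017), and replicates 2 and 3 held a median of 0% at both. This median lies at the counting limit, since 5 of the 12 positions had tags in asexual female replicate 1, 7 in all. Of the 20 positions, 19 had tags there, 261 in all. A small share of male replicate 1 is therefore not excluded. With minimums of 5 and 20 TPM the 1.19% became 0.783% each (permutation p = 0.0278 and 0.0062). The 1.19% lay above 0.415%, the bound set for a fixed share of male replicate 2, so this test cannot decide. The 1.19% is a share of male replicate 2 and the 0.415% of the male mean. At scaffold 10571, however, the share of male replicate 2 was also below 1.19%, with 112.6 TPM in asexual female replicate 1 and 40879 in male replicate 2. A fixed share of male replicate 2, taken from the other clusters, predicted 35.9 tags (25 to 48) at scaffold 23 (319987, plus). That cluster had 46 in asexual female replicate 1, 8916 in male replicate 2 and 0 in male replicate 1. Of the 17, only scaffold 10571 (1471 tags, 1482 to 1636 predicted), scaffold 36 at 524767 (115, 117 to 163) and scaffold 32 (42, 0 to 4) lay outside. Something else that these 2 libraries share stays open too. A male among the animals of asexual female replicate 1 cannot be told apart from tags or RNA of male replicate 2, since the yield of RNA from 1 male, which would set the 0.371%, is not known here.

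Narrow start regions were overrepresented among clusters higher in males than in asexual females. Tag number does not account for it, since the share exceeded that of matched clusters by 20.0 percentage points, nor do single positions, without which the excess was 24.1 points. Pooling states that start at different positions would widen shared clusters. With widths from male tags alone, at clusters with at least 50 male tags, the excess was 27.6 points (1406 of 1688 against 55.7% matched, permutation p = 0.0002, the smallest that 10000 draws can give). These widths still used cluster ends from all libraries and only positions with at least 10 tags over all libraries. Female tags can thus keep outer positions in shared clusters that are dropped from clusters higher in males. An effect of pooling therefore stays open. An excess was not particular to clusters higher in males. Clusters higher and lower in sexual than in asexual females were narrow in 79.7% and 78.0% of cases, against 57.0% and 63.7% after matching. Those more than 2-fold lower in males than in asexual females went the other way (58.9% against 63.8%). A biological difference, such as promoters of another class among clusters higher in males, remains a hypothesis, since promoter sequences were not tested.

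At 30 clusters with at least 50 TPM in sexual females and less than 1 part in 100 of that in males, asexual female replicates 1, 2 and 3 had a median of 0.0763%, 0.591% and 0.277% of the sexual female level.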
